A study of Mus musculus with 24 samples.

How the data were processed

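The study measured transcripts in 24 libraries of mouse salivary gland organoids, 3 in each of 8 groups given by 2 days after irradiation or sham irradiation of the gland (14 and 90), 2 passages of the culture (1 and 2) and 2 treatments. The cells were grown in Matrigel in a defined medium with EGF, FGF2, insulin and dexamethasone among its additions, per the labels' protocols. RNA was isolated with a column kit and DNase, and libraries were made with the QuantSeq kit, which primes at the poly(A) tail and reads the 3' end of transcripts, per the labels' protocols. A gene's count in such a library therefore does not grow with its length, and isoforms that share a 3' end are not told apart. The radiation dose is not given in the sources used here.

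The authors deposited raw read counts per gene, 1 file per library, with Ensembl mouse gene identifiers and no normalization. The submitters' processing notes name bcl2fastq and the genome build GRCm39; the aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Overlapping genes, antisense partners and near-identical copies could therefore have shared or split reads. Some such genes are marked as uncertain below, but not every gene with close copies is. Each file held 47643 genes and 5 further lines that name no gene, which stayed out of library sizes and tests. Reads on no gene came to 11.5% to 26.5% of a library (median 15.9%) and ambiguous reads to 0.259% to 0.451%. Gene symbols were taken by identifier from a reference annotation of an older build, used for names only, so no coordinates are printed. Of the identifiers 47224 matched, and the others held 0.01% of the counts. Counts on genes came to 1151608 to 3189466 per library, and 24858 genes had no count in any library. Replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 2.20 to 29.5), so none was counted as a duplicate.

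Groups were taken from the labels. The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter on the 8 groups, which left 10563 genes, and 1 mean per group fitted to all 24 libraries, so that the groups shared an estimate of the spread. Adjusted p-values are Benjamini-Hochberg over the tested genes, two-sided, and a gene was called at 0.05. The SE of a log2 fold change was worked back from the test, as its absolute value over the square root of the F statistic. It was not estimated separately. There were 12 comparisons: IR against sham in each day and passage, the interactions of IR with day in each passage and with passage in each day, and passage and day in the sham groups. Values per library are CPM with TMM factors, with mean ± SD over 3 libraries. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical, and passage 2 was grown from passage 1, so the passages are not independent. A fold against a group with no count was computed against a floor of 3 counts over the group, which covers counting error only.

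Gene lists of pathways and cell types, 34 in all, were fixed together with the comparisons, the tests, the named-gene rule and most alternatives before the data were examined. The 31 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Members were counted over all tested genes and adjusted over the list alone. For each comparison of IR with sham, the rule named 10 fixed genes whatever their result, then up to 6 called genes in each direction with the largest fold, a mean of at least 5 CPM and no overlap between the libraries of the groups, then up to 3 called members with the smallest p of each list that was called or had 2 or more called members. No overlap arises by chance for 10% of genes with 3 libraries against 3. For the other comparisons the rule took 4 genes in each direction, with non-overlap not required for interactions, and 2 members per list, or, where none was called, the 3 with the smallest p in each direction. Predicted genes were left out of the choice by size, and 1 gene that the rule named for day in passage 1 is not reported.

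The alternatives were DESeq2 1.42.0, median-of-ratios factors or total counts in edgeR, no filter or a stricter filter of 5 CPM in 3 libraries, only the compared groups, the replicate number as a block, and each library left out in turn. Added after the data were seen were the share of counts on Gm42418 as a covariate, the ribosomal RNA genes left out, 3 libraries with a deviating Gm42418 share left out, and the mean of the 4 IR effects. The closing section gives their effect. The scripts were tested on simulated counts drawn from the means and library sizes of the real ones, with 100 genes changed by 2-fold and 100 by 4-fold. In the simulated comparison of IR with sham at day 90 and passage 2, 42% and 90% of these were recovered, with 7 false calls among 10563 genes. In the simulated interaction of IR with passage at day 14 it was 14% and 71%, with 2 false calls, so 2-fold differences of effects were mostly beyond the depth and the number of libraries. The most false calls in a simulated comparison were 11, for IR with sham at day 14 and passage 1. Each gene was drawn independently, so shifts that many genes share within a library were not covered. The false calls in the real libraries may therefore be more. Tables were handled with pandas 2.3.3 in Python 3.11.15 and drawn with matplotlib 3.10.9. Gene structure and sequence were not analysed here.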

Results

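Gene expression was measured in organoids, small epithelial cultures grown in Matrigel from stem and progenitor cells of the salivary glands of C57BL/6 mice. The glands had been irradiated (IR) or sham-irradiated, and were taken 14 or 90 days later. Cultures of passage 1 and of passage 2 were sequenced, which gave 8 groups of 3 libraries and 24 libraries in all. The series title names microenvironmental Bmp4 and the regenerative response after irradiation, and Bmp4 was followed in each comparison. The questions were how irradiation of the gland changed the organoids, and whether that change differed with the time after irradiation and with passage. Counts on genes ranged from 1151608 to 3189466 per library, with a median of 2091528.5. Between 13402 and 15539 genes had at least 1 count. Gm42418, a predicted gene whose locus overlaps a ribosomal RNA repeat, took 11.8% to 29.0% of the gene counts of a library, and mitochondrial ribosomal RNA took 8.35% to 15.8%. Without these ribosomal genes 717549 to 2545671 counts were left per library, so genes at a few CPM, counts scaled to a common library size, rest on few reads.

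At day 14 and passage 1, the antioxidant genes as a list were higher in organoids of irradiated glands than in sham organoids. Aldh1a3, a retinaldehyde dehydrogenase used as a progenitor marker, went from 41.6 ± 8.13 CPM in sham to 264 ± 144 CPM in IR organoids (SD, n = 3), a log2 fold change of 2.65 (SE 0.36, adjusted p = 0.00207). Of the 20 tested NRF2 antioxidant genes, 5 were higher and 0 lower over all genes, and 13 were higher adjusted over the list alone. They included Srxn1, which reduces oxidised peroxiredoxins (1.69, SE 0.31, adjusted p = 0.0265), and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (1.68, SE 0.32, adjusted p = 0.0296). Also called were G6pdx, which opens the pentose phosphate pathway (1.18, SE 0.22), and Gsta4, a glutathione transferase (2.98, SE 0.60, adjusted p = 0.0332). The NRF2 list was called higher as a group, and the call held with an estimated correlation between genes (adjusted p = 0.0301). The calls of these 4 NRF2 genes were lost without any of the 3 sham replicates or IR replicate 1 or 2 (adjusted p up to 0.283), and that of Aldh1a3 without sham replicate 1 (adjusted p up to 0.0606).

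Of 25 squamous differentiation genes at day 14 and passage 1, 2 were higher and 0 lower over all genes, and 15 were higher adjusted over the list alone. S100a8, a subunit of calprotectin, rose from 2.82 ± 1.12 to 42.1 ± 29.9 CPM (log2 fold change 3.76, SE 0.70, adjusted p = 0.0265). Cdsn, which encodes corneodesmosin, had a log2 fold change of 4.54 (SE 0.96, adjusted p = 0.0460). The squamous list was called with the preset correlation and with fry (adjusted p = 0.0396), but not with the estimate (adjusted p = 0.108 with an estimated correlation). Psca, a cell surface antigen, was higher by 4.60 (SE 0.86). The near-identical prolactin family members Prl2c2 (7.02, SE 1.12) and Prl2c3 (5.56, SE 1.14) were called higher but may share reads and stay uncertain. Procr, the protein C receptor of the progenitor list, was higher by 2.30 (SE 0.51, adjusted p = 0.0474). Of the 22 progenitor genes, 2 were called higher over all genes. Id2, an inhibitor of basic helix-loop-helix factors, was the 1 called member of the 11 tested BMP-SMAD targets (1.25, SE 0.24, adjusted p = 0.0296). Adjusted over the list alone, 3 were higher and 1 lower (adjusted p = 0.148 with an estimated correlation). Lower in IR organoids were Igfbp5, an insulin-like growth factor binding protein (−4.36, SE 0.94), and Tgfbr3, the TGF-beta co-receptor betaglycan (−3.38, SE 0.74). So were Gas1, a hedgehog co-receptor (−2.55, SE 0.50), Pdzd2 (−1.69, SE 0.36) and Bnc2 (−1.39, SE 0.30), and the 5 had adjusted p from 0.0296 to 0.0474. The calls of the genes of this paragraph were lost without any of the 3 sham replicates or IR replicate 1 or 2, except that Prl2c2 kept its call without IR replicate 1. That of Bnc2 was lost also without IR replicate 3 (adjusted p up to 0.333).

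At this time and passage Bmp4 (ENSMUSG00000021835), the ligand named in the series title, stood at 4.92 ± 2.69 CPM in sham and 8.19 ± 3.49 CPM in IR organoids (log2 fold change 0.74, SE 0.48, adjusted p = 0.636) and was not called. The BMP target genes Id1 (1.36, SE 0.50, adjusted p = 0.293) and Id3 (1.22, SE 0.52, adjusted p = 0.384) were not called either. Among the other genes fixed beforehand, the p53 targets Cdkn1a (0.94, adjusted p = 0.145) and Mdm2 (0.24), and the proliferation marker Mki67 (−0.50) did not pass. The basal keratins Krt5 (0.01) and Krt14 (0.37), the ductal keratin Krt19 (−0.32) and the acinar water channel Aqp5 (−1.14, adjusted p = 0.322) did not pass. The 41 interferon response genes had a median log2 fold change of −2.87 with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.441 with an estimated correlation). The 19 MHC class I genes (median −0.89, adjusted p = 0.515 with an estimated correlation) and 22 basal duct genes (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.515 with an estimated correlation) were called only with the preset correlation, as were 27 senescence genes (adjusted p = 0.211 with an estimated correlation). The 6 myoepithelial genes (adjusted p = 0.108 with an estimated correlation) and 4 mesenchymal genes (adjusted p = 0.108 with an estimated correlation) were called with fry as well (adjusted p = 0.0396 and 0.0247). In all, edgeR called 36 of 10563 genes, 31 higher and 5 lower, against 1160 at an unadjusted p under 0.05 and 123 with DESeq2. The calls were 0 without sham replicate 1, 1 without sham replicate 2, 2 without sham replicate 3, 2 without IR replicate 1, 1 without IR replicate 2 and 146 without IR replicate 3. Aldh1a3 lost its call without sham replicate 1, and its adjusted p ranged from 1.54e-29 to 0.0606 over the alternatives.

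At day 14 and passage 2, the 2 called genes were of the luminal list. Krt8, a keratin of simple and luminal epithelium, was at 44.9 ± 5.01 CPM in sham and 105 ± 25.9 CPM in IR organoids (SD, n = 3), a log2 fold change of 1.22 (SE 0.21, adjusted p = 0.0454). Wfdc2, a secreted ductal protease inhibitor, went from 363 ± 78.1 to 926 ± 258 CPM (1.35, SE 0.20, adjusted p = 0.00881). These were 2 of the 22 tested luminal duct and ionocyte genes, and 5 were higher adjusted over the list alone (adjusted p = 0.389 with an estimated correlation). Of 24 YAP and regeneration genes, 0 were called over all genes and 4 were higher adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). Bmp4 was at 0.666 ± 0.593 CPM in sham and 3.74 ± 2.10 CPM in IR organoids (2.24, SE 0.74, adjusted p = 0.562). Id1 was at 11.5 ± 1.28 and 46.2 ± 30.1 CPM (1.95, SE 0.55, adjusted p = 0.496) and Id3 at 28.5 ± 5.46 and 93.9 ± 47.3 CPM (1.70, SE 0.56, adjusted p = 0.562), and none of these 3 was called. IR replicate 3 of this group lay near the sham libraries, with Bmp4 at 1.81 CPM and Id1 at 11.6 CPM. Its Gm42418 share of 17.2% stood apart from the other 2 replicates. Sham replicate 1 stood apart from the other sham libraries as well. By the mean log2 CPM of the interferon list it lay with IR replicates 1 and 2 (2.03, 2.35 and 2.70). Sham replicates 2 and 3 lay with IR replicate 3 (5.83, 5.66 and 5.68). Mdm2 (0.88, adjusted p = 0.462), Cdkn1a (0.31), Mki67 (−0.37), Krt5 (−0.69), Krt14 (−0.61), Krt19 (−0.67) and Aqp5 (0.28) did not pass. Lists called only with the preset correlation were the lower basal duct (adjusted p = 0.414 with an estimated correlation) and squamous genes (adjusted p = 0.558 with an estimated correlation). The same held for the lower myoepithelial (adjusted p = 0.389 with an estimated correlation), interferon (adjusted p = 0.655 with an estimated correlation) and MHC class I genes (adjusted p = 0.655 with an estimated correlation). The higher NF-kappaB (adjusted p = 0.434 with an estimated correlation) and p53 lists (adjusted p = 0.434 with an estimated correlation) were alike in this. Without 1 library the MHC class I median changed sign, while the direction of its camera test did not. edgeR called 2 genes, both higher, against 711 at an unadjusted p under 0.05 and 17 with DESeq2. The calls were 0 without sham replicate 2, sham replicate 3, IR replicate 1 or IR replicate 2, which ended those of Krt8 and Wfdc2. They were 7 without sham replicate 1 and 38 without IR replicate 3. With only the compared groups fitted the count was 0 as well, and the replicate block kept 1 of the 2 calls.

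At day 90 and passage 1, Krt8 was again higher after irradiation, at 116 ± 18.9 CPM in sham and 258 ± 30.1 CPM in IR organoids (SD, n = 3, log2 fold change 1.16, SE 0.20, adjusted p = 0.0392). Pim1, a serine/threonine kinase induced by cytokines, rose from 21.4 ± 3.04 to 64.9 ± 10.6 CPM (1.58, SE 0.30, adjusted p = 0.0481). Slc16a11, a monocarboxylate transporter family member, was higher by 2.20 (SE 0.41, adjusted p = 0.0481). Tiam1, an activator of the GTPase Rac, fell from 113 ± 19.5 to 55.3 ± 6.95 CPM (−1.02, SE 0.17, adjusted p = 0.0392). Serp1, a protein of the endoplasmic reticulum, had a log2 fold change of −0.80 (SE 0.15, adjusted p = 0.0481). Bmp4 was at 5.20 ± 1.29 CPM in sham and 15.7 ± 1.54 CPM in IR organoids (1.57, SE 0.43, adjusted p = 0.127) and was not called. Id1 (0.87, adjusted p = 0.434), Id3 (1.24, adjusted p = 0.297), Mdm2 (0.62), Cdkn1a (−0.14) and Mki67 (−0.19) did not pass. Neither did Krt5 (−1.03, adjusted p = 0.310), Krt14 (−0.76, adjusted p = 0.332), Krt19 (−1.92) or Aqp5 (−0.29). Of 22 luminal genes 1 was higher over all genes and 7 adjusted over the list alone (adjusted p = 0.297 with an estimated correlation). Of 22 basal duct genes 0 were called over all genes and 7 were lower adjusted over the list alone (adjusted p = 0.297 with an estimated correlation). The 24 YAP and regeneration genes had 5 higher adjusted over the list alone (adjusted p = 0.297 with an estimated correlation). The squamous (adjusted p = 0.603 with an estimated correlation), interferon (adjusted p = 0.603 with an estimated correlation), and MHC class I lists (adjusted p = 0.894 with an estimated correlation) were called lower only with the preset correlation. The same held for the glycolysis (adjusted p = 0.595 with an estimated correlation) and myoepithelial lists (adjusted p = 0.494 with an estimated correlation). The Gm42418 share moved with these groups: it was 28.6%, 15.9% and 11.8% in the sham libraries and 29.0%, 26.9% and 27.0% in the IR libraries. edgeR called 5 genes, 3 higher and 2 lower, against 1339 at an unadjusted p under 0.05 and 86 with DESeq2. It called 0 with the Gm42418 share as a covariate, where the MHC class I median turned from −0.31 to 0.18. The calls were 25 without sham replicate 1, 1 without sham replicate 2, and 0 without sham replicate 3 or any IR replicate.

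At day 90 and passage 2, organoids of irradiated glands differed most from sham in number of called genes among the 4 comparisons of IR with sham. Bmp4 rose from 1.03 ± 0.934 CPM in sham to 13.7 ± 1.76 CPM in IR organoids (SD, n = 3, log2 fold change 3.62, SE 0.51, adjusted p = 0.000353). Of the BMP target genes 3 of the Id family rose with it, Id1 from 33.7 ± 23.7 to 171 ± 65.0 CPM (2.33, SE 0.47, adjusted p = 0.00577), and Id3 from 36.5 ± 39.3 to 263 ± 90.1 CPM (2.83, SE 0.54, adjusted p = 0.00409). Id2 was higher by 1.48 (SE 0.24, adjusted p = 0.00142). Of 11 tested BMP-SMAD targets, 4 were higher and 0 lower over all genes, and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0760 with an estimated correlation). Of 17 BMP ligands, receptors and antagonists, 2 were higher and 1 lower, and 3 and 3 adjusted over the list alone. Fstl1, a secreted follistatin-like glycoprotein, was higher (2.43, SE 0.39, adjusted p = 0.00107), and Rgma, a BMP co-receptor, was lower (−1.34, SE 0.31, adjusted p = 0.0139). The call of Rgma was lost without sham replicate 1, IR replicate 2 or IR replicate 3 (adjusted p up to 0.122). The calls of Bmp4 and Id2 held under every alternative run. Those of Id1 and Id3 were lost when only the 2 compared groups were fitted (adjusted p from 2.35e-23 to 0.0639 and from 1.89e-36 to 0.0886 over their alternatives), as were those of Fstl1 and Rgma, and that of Rgma also with the Gm42418 share as a covariate (adjusted p up to 0.0622 and 0.122).

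Called members of the luminal list, among them Krt8, Krt18 and Krt7 but not Krt19 (−2.41, not called), rose in the same comparison. Krt8 went from 40.8 ± 6.61 to 137 ± 27.3 CPM (log2 fold change 1.75, SE 0.21, adjusted p = 0.000195). Its partner Krt18 (1.58, SE 0.22), Krt7 (1.56, SE 0.29) and Scnn1a, a subunit of the epithelial sodium channel (2.67, SE 0.44, adjusted p = 0.00150), rose too. Of 22 luminal duct and ionocyte genes, 11 were higher and 0 lower over all genes, and 13 and 1 adjusted over the list alone (adjusted p = 0.0666 with an estimated correlation). Fn1, fibronectin, rose from 82.6 ± 42.5 to 1489 ± 786 CPM (4.17, SE 0.52, adjusted p = 0.000195). Thbs1, thrombospondin, was higher by 2.06 (SE 0.29, adjusted p = 0.000353). Of 19 TGF-beta targets and matrix genes, 5 were higher and 1 lower, and 8 and 2 adjusted over the list alone (adjusted p = 0.0760 with an estimated correlation). Of 24 YAP and regeneration genes, 8 were higher and 2 lower, and 10 and 2 adjusted over the list alone (adjusted p = 0.0760 with an estimated correlation). Among them were Edn1, endothelin, at 2.10 (SE 0.38) and Clu, clusterin, at 1.93 (SE 0.39). Among single genes chosen by size were Gpx3, a secreted glutathione peroxidase (5.68, SE 0.93, adjusted p = 0.00133), and Nox4, an NADPH oxidase (3.95, SE 0.55). Others were the lectin-like receptor gene Klrb1f (3.97, SE 0.58) and Scx, a transcription factor known from tendon (3.85, SE 0.59). Sult1a1, a sulfotransferase, was higher by 4.36 (SE 0.89) and was 1 of 2 called among 17 glucocorticoid response genes. With only the compared groups fitted, Scnn1a, Edn1, Clu, Gpx3 and Klrb1f lost their calls, and Clu also with the Gm42418 share as a covariate (adjusted p up to 0.119). The other genes of this paragraph called here kept theirs under every alternative run.

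The called members of the squamous and basal duct lists fell at day 90 and passage 2, while neither list held its call with an estimated correlation, though both did with fry. Of 25 squamous differentiation genes, 14 were lower and 0 higher over all genes, and 20 were lower adjusted over the list alone (adjusted p = 0.0760 with an estimated correlation). S100a8 fell from 108.5 ± 43.7 to 6.06 ± 0.555 CPM (−4.15, SE 0.56, adjusted p = 0.000345) and S100a9, its calprotectin partner, by −4.68 (SE 0.77, adjusted p = 0.00133). Dsg3, a desmosomal cadherin, fell by −1.93 (SE 0.33, adjusted p = 0.00175). Krt6b, whose near-identical copy Krt6a may share its reads, had a log2 fold change of −6.94 (SE 1.46) and lost its call without IR replicate 2 or 3 (adjusted p up to 0.0593). Of 22 basal duct genes, 4 were lower and 0 higher, and 10 were lower adjusted over the list alone (adjusted p = 0.138 with an estimated correlation). Trp63, the p63 regulator of basal identity, fell from 120.5 ± 41.2 to 54.5 ± 9.97 CPM (−1.14, SE 0.25, adjusted p = 0.00939). It lost its call without sham replicate 1 or IR replicate 3 (adjusted p up to 0.0798). Dsg3 and Trp63 lost their calls with only the compared groups fitted (adjusted p up to 0.0757 and 0.0798). Krt5 (−1.38, SE 0.44, adjusted p = 0.0705) and Krt14 (−0.99, SE 0.33, adjusted p = 0.0965) were not called.

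Called progenitor and acinar genes moved in mixed directions at day 90 and passage 2. Of 22 progenitor genes, 4 were higher and 2 lower over all genes, and 4 and 3 adjusted over the list alone. Lgr6, a receptor for R-spondins, was at 5.37 ± 4.74 CPM in sham and 51.4 ± 27.7 CPM in IR organoids (log2 fold change 3.23, SE 0.55, adjusted p = 0.00175). Rarb, a retinoic acid receptor, was higher (4.73, SE 1.07) and lost its call without sham replicate 3, IR replicate 2 or IR replicate 3 (adjusted p up to 0.0839). Sox2, a transcription factor of progenitor cells (−6.38), and the basal keratin Krt15 (−3.08, SE 0.78) were lower. Both lost their calls without sham replicate 1, IR replicate 2 or IR replicate 3 (adjusted p up to 0.129 and 0.126). Of 15 acinar genes, 2 were higher and 2 lower, and 2 and 4 adjusted over the list alone. Slc12a2, the sodium-potassium-chloride cotransporter of secretory cells, rose from 300.1 ± 39.3 to 706 ± 112 CPM (1.23, SE 0.23, adjusted p = 0.00424). Chrm3, a muscarinic receptor, was higher by 1.28 (SE 0.28), a call lost without sham replicate 1 (adjusted p = 0.0667). Dcpp3, a secreted protein of a multigene family, had no count in IR organoids and was at least 24.9-fold lower there, from a floor of 3 counts over the group. It stays uncertain because its copies may share reads. By the same floor Nkx2-3 was at least 44.4-fold lower, and Serpinb3a, also of a family of close copies, at least 50.4-fold lower. All 3 calls were lost without sham replicate 1, IR replicate 2 or IR replicate 3 (adjusted p up to 0.124, 0.249 and 0.143). Those of Nkx2-3 and Serpinb3a were lost also without IR replicate 1, and that of Serpinb3a without sham replicate 3. With only the compared groups fitted Lgr6, Sox2, Krt15 and Serpinb3a lost their calls (adjusted p up to 0.202), and with the Gm42418 share as a covariate Rarb and Serpinb3a did (adjusted p up to 0.143).

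Of 23 glycolysis and hypoxia genes in this comparison, 3 were lower and 0 higher, and 7 were lower adjusted over the list alone (adjusted p = 0.377 with an estimated correlation). Of 12 Notch pathway genes, 2 were lower, and 2 were higher and 6 lower adjusted over the list alone. Of 20 FGF and EGF response genes, 1 was higher and 2 lower, and 2 and 3 adjusted over the list alone. Spry2, a feedback inhibitor of receptor tyrosine kinases, was lower by −1.40 (SE 0.23, adjusted p = 0.00154), a call lost with only the compared groups fitted (adjusted p up to 0.0522). Of 20 NRF2 antioxidant genes 2 were higher, and 2 were higher and 1 lower adjusted over the list alone. Of 27 senescence genes 2 were higher, and 4 were higher and 1 lower adjusted over the list alone. Of 23 unfolded protein response genes 1 was higher and 1 lower on both counts. Of 6 myoepithelial genes 1 was lower, and 2 were lower adjusted over the list alone (adjusted p = 0.304 with an estimated correlation). The 41 interferon genes (median −1.27, adjusted p = 0.636 with an estimated correlation) and 19 MHC class I genes (median −0.63, adjusted p = 0.636 with an estimated correlation) had 0 called members over all genes and 0 adjusted over the list alone. Cdkn1a (−0.23, adjusted p = 0.714), Mdm2 (0.41, adjusted p = 0.371), Mki67 (0.43, adjusted p = 0.756), Krt19 (−2.41, adjusted p = 0.136) and Aqp5 (−0.37, adjusted p = 0.712) were not called. The Gm42418 share was 15.5%, 14.3% and 13.1% in the sham libraries and 13.5% in IR replicate 1 and 24.3% in IR replicate 2, with IR replicate 3 close to the latter. In all, edgeR called 520 genes, 314 higher and 206 lower, 358 of them by 2-fold or more, against 1929 at an unadjusted p under 0.05 and 628 with DESeq2. The calls were 255 without sham replicate 1, 304 without sham replicate 3, 143 without IR replicate 2, 137 without IR replicate 3 and 1194 without IR replicate 1. They were 225 with the Gm42418 share as a covariate and 85 with only the compared groups fitted. Of 52 called genes that the rule named here, 36 stayed called with the covariate, 18 with only the compared groups and 13 under every alternative run.

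**Figure D1:**
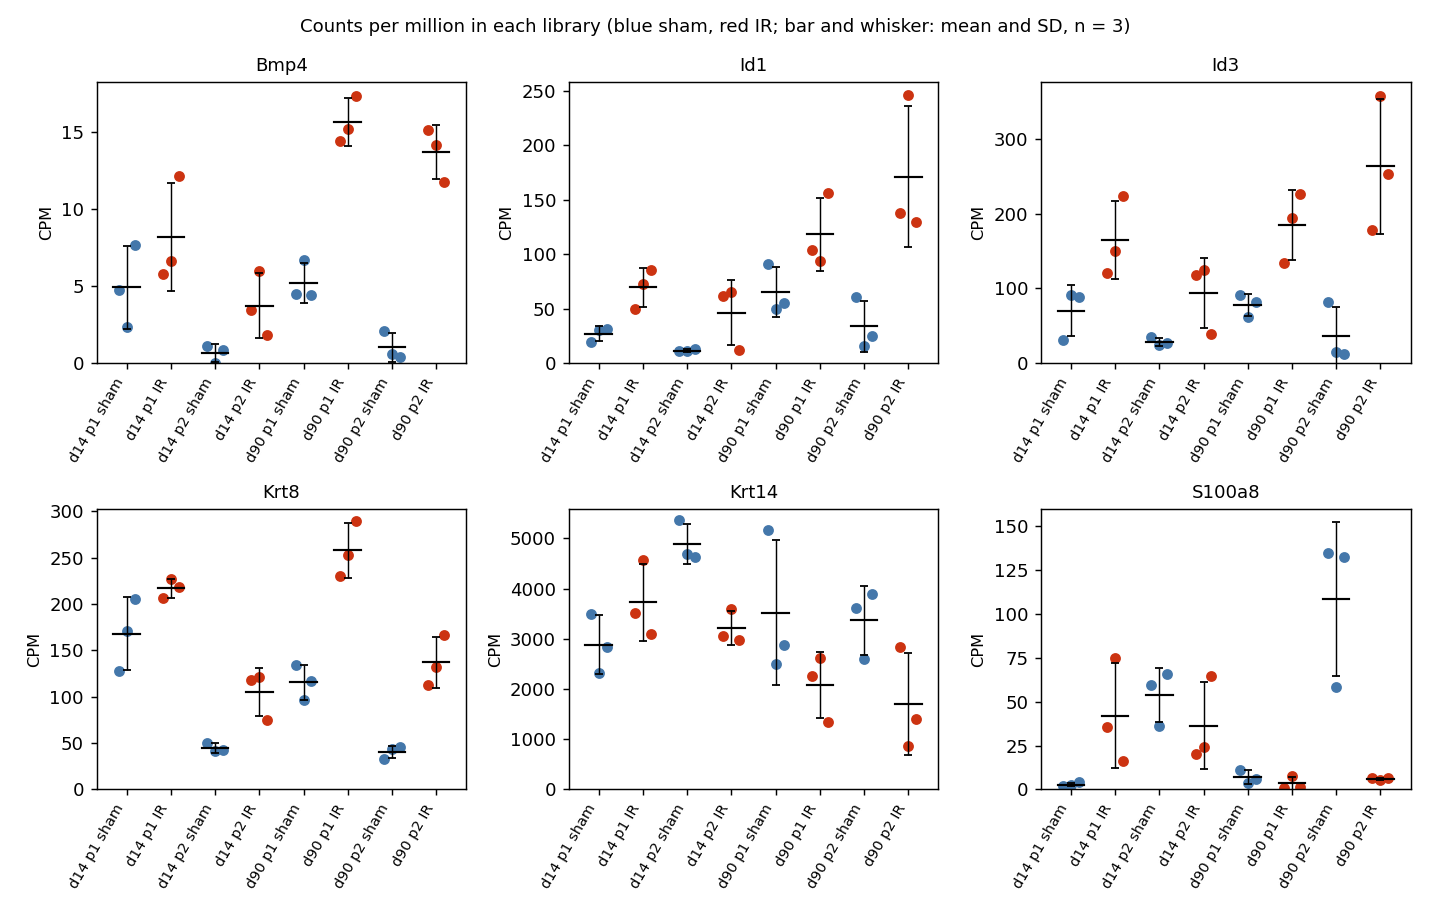
Each point is the CPM of Bmp4, Id1, Id3, Krt8, Krt14 or S100a8 in 1 library, for the 8 groups on the x axis (d, day and p, passage), with sham in blue, IR in red, and the mean and SD of the 3 libraries as bar and whisker. At day 90 and passage 2 Bmp4 averaged 1.03 CPM in sham and 13.7 CPM in IR organoids, and S100a8 108.5 and 6.06 CPM.

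Whether the IR effect differed with the time after irradiation was tested as an interaction. In passage 1, Tmprss4, a membrane serine protease of epithelia, was at 39.7 ± 4.82 CPM in sham and 126 ± 53.4 CPM in IR organoids at day 14, and at 89.1 ± 3.84 and 39.3 ± 15.7 CPM at day 90 (SD, n = 3). Its IR effect was lower at day 90 by a log2 of −2.85 (SE 0.39, adjusted p = 0.00222). Car6, a secreted carbonic anhydrase of acinar cells, was at 10.0 ± 4.28 and 74.7 ± 47.8 CPM at day 14, and at 16.6 ± 10.1 and 4.10 ± 1.85 CPM at day 90 (−4.76, SE 0.78, adjusted p = 0.0282). Car6 was the 1 called member of 15 acinar genes, of which 3 were lower adjusted over the list alone (adjusted p = 0.257 with an estimated correlation). Of 25 squamous genes, 0 were called over all genes and 15 were lower adjusted over the list alone (median −3.17, adjusted p = 0.169 with an estimated correlation). Of 20 NRF2 genes it was 0 and 7 (median −1.04, adjusted p = 0.182 with an estimated correlation). The lower basal duct (adjusted p = 0.772 with an estimated correlation) and higher glucocorticoid lists (adjusted p = 0.593 with an estimated correlation) were called only with the preset correlation. edgeR called 2 genes, both lower, against 857 at an unadjusted p under 0.05 and 24 with DESeq2. The call of Tmprss4 held without any single library. That of Car6 was lost without any day 14 library except IR replicate 3 and without day 90 sham replicate 1, IR replicate 2 or IR replicate 3 (adjusted p up to 0.133). The count was 23 without day 14 IR replicate 3, 3 without day 90 sham replicate 2 or IR replicate 1, 2 without day 90 sham replicate 3, and 1 without each of the other libraries.

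In passage 2, Ccl8, a chemokine, was at 1.10 ± 1.02 CPM in sham and 5.52 ± 3.29 CPM in IR organoids at day 14, and at a mean of 20.8 CPM (12.3 to 28.2 CPM) and 1.79 ± 0.253 CPM at day 90 (SD, n = 3). The IR effects differed by −5.73 on the log2 scale (SE 0.90, adjusted p = 0.0229). Bmp4, Id1, Id3 and Krt8 were not called in this interaction, nor in that of passage 1, so a different IR effect on them at the 2 times was not shown. The squamous list (median −1.51, adjusted p = 0.328 with an estimated correlation) had 5 genes lower adjusted over the list alone and 0 over all genes. The luminal (2 higher adjusted over the list alone, adjusted p = 0.328 with an estimated correlation), and TGF-beta lists (2 higher adjusted over the list alone, adjusted p = 0.328 with an estimated correlation) had 0 members called over all genes. So had the acinar (adjusted p = 0.328 with an estimated correlation), glycolysis (adjusted p = 0.779 with an estimated correlation) and cholesterol lists (adjusted p = 0.814 with an estimated correlation). edgeR called 1 gene against 543 at an unadjusted p under 0.05 and 2 with DESeq2. The count was 0 without sham replicate 2 or 3 or IR replicate 2 of day 14 and without sham replicate 2 or 3 or IR replicate 2 or 3 of day 90, and 10 without day 90 IR replicate 1. The call of Ccl8 was lost without each of the 7 libraries that left 0 calls (adjusted p up to 0.205).

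Whether the IR effect differed between passages was tested in the same way, and no gene was called. At day 14, S100a8 (−4.29, SE 0.86), Gsta4 (−4.02, SE 0.81) and Slc48a1, a heme transporter (−1.80, SE 0.38), had the smallest p among genes with a lower IR effect in passage 2 (adjusted p = 0.181 each). Ltf, lactoferrin (2.64, SE 0.59, adjusted p = 0.181), Cp, ceruloplasmin (2.33, SE 0.51, adjusted p = 0.181) and Smo, the hedgehog signal transducer (2.23, SE 0.52, adjusted p = 0.195), had the smallest p among those with a higher effect. As a group, the 25 squamous genes had a lower IR effect in passage 2 than in passage 1 (median −2.82, with 0 called over all genes and 14 lower adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.0428). With fry that call was lost. The 20 NRF2 genes had a lower effect too (median −1.18, 0 called over all genes and 12 lower adjusted over the list alone), and this held with an estimated correlation (adjusted p = 0.0316). The interferon list had a median of 2.01 with 0 members called over all genes (adjusted p = 0.848 with an estimated correlation). Its direction rested on 1 library, as the median was −0.44 without passage 2 IR replicate 3. edgeR called 0 genes at day 14, against 729 at an unadjusted p under 0.05 and 20 with DESeq2. It called 24 without passage 1 IR replicate 3 and 5 without passage 2 IR replicate 3.

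At day 90, the genes with the smallest p for a difference between passages were Gpx3 (6.38, SE 1.21, adjusted p = 0.288), the dynein chain Dync1i1 (4.25, SE 0.86, adjusted p = 0.302) and Klrb1f (3.71, SE 0.80, adjusted p = 0.302) with a higher effect in passage 2. With a lower effect they were Serpinb1a, a protease inhibitor (−2.97, SE 0.76, adjusted p = 0.568), Mrps5, a mitochondrial ribosomal protein (−0.73, SE 0.21, adjusted p = 0.903) and the phosphatase Ptpn3 (−1.14, SE 0.33, adjusted p = 0.969). None was called, and Bmp4 was not called either, so its IR effect was not shown to differ between passages. The TGF-beta list had 3 members higher adjusted over the list alone and 0 over all genes (median 0.44, adjusted p = 0.118 with an estimated correlation). The luminal (2 higher adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), and BMP-SMAD lists (adjusted p = 0.271 with an estimated correlation) had 0 members called over all genes. So had the squamous (adjusted p = 0.271 with an estimated correlation) and cholesterol lists (adjusted p = 0.927 with an estimated correlation). edgeR called 0 genes against 407 at an unadjusted p under 0.05 and 3 with DESeq2, and 9 without passage 2 IR replicate 1.

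The sham groups gave the background of passaging. At day 14, Krt8, Krt18 and Krt7 of the luminal list were lower in passage 2 than in passage 1. Krt8 fell from 168 ± 39.2 to 44.9 ± 5.01 CPM (SD, n = 3, log2 fold change −1.91, SE 0.21, adjusted p = 7.8e-05). Krt18 was at −1.79 (SE 0.23) and Krt7 at −2.08 (SE 0.30). Of 22 luminal genes, 6 were lower and 0 higher over all genes and 9 were lower adjusted over the list alone. The call of the list held with an estimated correlation (adjusted p = 0.00305). Fn1 fell from 1156 ± 105 to 93.9 ± 40.3 CPM (−3.63, SE 0.51, adjusted p = 0.000500). It was 1 of 2 lower among 19 TGF-beta and matrix genes, with 6 lower adjusted over the list alone. That list and the YAP list, with 4 of 24 lower and 9 lower adjusted over the list alone, were called lower with an estimated correlation as well (adjusted p = 0.0261 each). Clu was lower by −2.36 (SE 0.40, adjusted p = 0.00311), and Ppp1r9a, a neurabin of the actin cytoskeleton, by −4.31 (SE 0.69, adjusted p = 0.00190). S100a8 rose from 2.82 ± 1.12 to 53.7 ± 15.6 CPM (4.19, SE 0.68, adjusted p = 0.00214), and Notch1 was higher by 1.15 (SE 0.21, adjusted p = 0.00612). These 8 genes kept their calls without any single library.

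Of 25 squamous genes at day 14, 3 were higher in passage 2 over all genes and 12 adjusted over the list alone (adjusted p = 0.136 with an estimated correlation), S100a9 among them (4.28, SE 0.89). Of 15 acinar genes 2 were lower and 4 adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). Slc12a2 was at −1.25 (SE 0.24) and Car6 at −3.44 (SE 0.83). Mucl2, a salivary mucin-like gene with no count in passage 2, was at least 27.8-fold lower there, from a floor of 3 counts over the group. The glucocorticoid list had 2 lower members on both counts (adjusted p = 0.227 with an estimated correlation), Pdk4 (−2.41, SE 0.52) and Sult1a1 (−3.66, SE 0.87). Bend7 (−4.59, SE 0.85), Fgd3 (−4.16, SE 0.79) and Thbs1 (−1.56, SE 0.29) were lower. The collagen Col23a1 (4.73, SE 1.06), the mitochondrial tRNA gene mt-Tc (4.90, SE 1.12) and Spry2 (1.13, SE 0.25) were higher. How mt-Tc entered libraries primed at the poly(A) tail was not tested, so its counts may not measure its expression. The Notch list (1 higher, and 3 adjusted over the list alone, adjusted p = 0.0908 with an estimated correlation), the FGF and EGF list (1 higher on both counts, adjusted p = 0.318 with an estimated correlation), and the basal duct list (adjusted p = 0.227 with an estimated correlation) were called higher with the preset correlation, and of these the Notch list with fry too (adjusted p = 0.0162). Called higher only with the preset correlation were the NRF2 list (adjusted p = 0.633 with an estimated correlation), the MHC class I list (adjusted p = 0.786 with an estimated correlation) and the interferon list (adjusted p = 0.820 with an estimated correlation). edgeR called 125 genes, 23 higher and 102 lower, against 1208 at an unadjusted p under 0.05 and 184 with DESeq2. The calls were 66, 55 and 49 without passage 1 sham replicate 1, 2 or 3 and 34 and 20 without passage 2 sham replicate 2 or 3. Each gene of this paragraph lost its call without 1 or more of the 6 libraries (adjusted p up to 0.239).

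At day 90, passage 2 sham organoids again held less Krt8 (116 ± 18.9 against 40.8 ± 6.61 CPM, adjusted p = 0.000529) and less Fn1 (911 ± 208 against 82.6 ± 42.5 CPM, −3.46, SE 0.50, adjusted p = 0.000824) than passage 1. Of 22 luminal genes, 8 were lower and 0 higher, and 12 lower and 1 higher adjusted over the list alone. The call held with an estimated correlation (adjusted p = 0.0277). Fstl1 (−2.86, SE 0.38, adjusted p = 0.000400), Car6 (−4.74, SE 0.74, adjusted p = 0.00231) and Mucl2 (−6.66, SE 1.00, adjusted p = 0.00231) were lower. S100a8 was higher (6.92 ± 3.97 against 108.5 ± 43.7 CPM, 4.05, SE 0.56, adjusted p = 0.000529). These 6 genes kept their calls without any single library. Bmp4 was lower by −2.23 (SE 0.55, adjusted p = 0.0436). It lost that call without any of the 3 passage 1 libraries or passage 2 sham replicate 2 or 3 (adjusted p up to 0.187). Klk1, a ductal kallikrein (−5.66, SE 1.04), and S100a9 (3.93, SE 0.71) lost theirs without passage 2 sham replicate 3 (adjusted p = 0.0536) and passage 1 sham replicate 3 (adjusted p = 0.0639). Krt7 (−1.52, SE 0.29) and Edn1 (−1.98, SE 0.38) lost theirs without passage 2 sham replicate 1 (adjusted p = 0.0534 and 0.0604).

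Of 39 cell cycle genes at day 90, 0 were called over all genes and 21 were lower in passage 2 adjusted over the list alone (median −1.06, adjusted p = 0.353 with an estimated correlation). The interferon (3 higher adjusted over the list alone, adjusted p = 0.353 with an estimated correlation), MHC class I (3 higher adjusted over the list alone, adjusted p = 0.359 with an estimated correlation) and immediate early lists (adjusted p = 0.404 with an estimated correlation) were called higher, with 0 members called over all genes. The cholesterol (adjusted p = 0.368 with an estimated correlation), nuclear OXPHOS (adjusted p = 0.353 with an estimated correlation) and DNA break repair lists (adjusted p = 0.381 with an estimated correlation) were called lower, with 0 members called over all genes. Of 25 squamous genes 3 were higher, and 4 adjusted over the list alone (adjusted p = 0.353 with an estimated correlation). Of 19 TGF-beta and matrix genes 2 were lower, and 5 adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Thbs1 was at −1.35 (SE 0.28). Of 24 YAP genes 3 were lower, and 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.318 with an estimated correlation). The p53 list (1 higher on both counts, Plk2 at 1.32, SE 0.26, adjusted p = 0.381 with an estimated correlation) and the NF-kappaB list (1 higher on both counts, Saa1 at 4.14, SE 0.78, adjusted p = 0.381 with an estimated correlation) were called higher. Of 3 tested immune genes, the myeloid genes Lyz2 (−5.71, SE 1.42) and Ctss (−5.18, SE 1.29) were lower in passage 2. There Lyz2 was at 0.101 ± 0.175 CPM against 8.07 ± 8.10 CPM in passage 1. Passage 1 sham replicate 1 held neither gene, so the groups overlapped. Without these 2 genes the immune list summed to 13, 22.5 and 18.4 CPM in passage 1 sham and 19.5, 17 and 16.1 CPM in passage 2 sham. A fall of the immune list beyond these 2 genes was thus not seen. Of 15 acinar genes 3 were lower, and 5 adjusted over the list alone, with Prol1 at −4.73 (SE 1.00). Of 27 senescence genes, Csf3, a granulocyte growth factor (2.82, SE 0.57), was higher and Tnfrsf11b, osteoprotegerin (−1.79, SE 0.44), lower. Ifi209, an interferon-induced gene, was higher by 3.78 (SE 0.75). edgeR called 144 genes, 47 higher and 97 lower, against 1474 at an unadjusted p under 0.05 and 212 with DESeq2. The calls were 91, 77 and 26 without passage 1 sham replicate 1, 2 or 3 and 65 and 39 without passage 2 sham replicate 1 or 3. Each single gene of this paragraph lost its call without 1 or more of the 6 libraries (adjusted p up to 0.181).

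Sham organoids of day 90 and day 14 were compared last, where age of the animal, culture round and library round cannot be separated. In passage 1 no gene was called. Among the smallest p were those of the transcription factor Klf7 (−1.29, SE 0.23), the transcriptional cofactor Cited2 (−1.16, SE 0.22) and the chaperone partner Chordc1 (0.82, SE 0.15), each with adjusted p = 0.0537. Next were Lpar6, a lysophosphatidic acid receptor (1.04, SE 0.20), and Zbtb7b (1.27, SE 0.26), with adjusted p = 0.0654. Of 17 glucocorticoid response genes, 0 were called over all genes and 6 were lower adjusted over the list alone (median −0.39, adjusted p = 0.0954 with an estimated correlation). Of 9 mitochondrially encoded genes it was 0 and 5 (median −0.58, adjusted p = 0.455 with an estimated correlation). The squamous (2 higher adjusted over the list alone), cholesterol, glycolysis and NRF2 lists were called higher and the MHC class I list lower with the preset correlation (adjusted p = 0.763 each with an estimated correlation). So was the lower myoepithelial list (adjusted p = 0.455 with an estimated correlation). edgeR called 0 genes against 1025 at an unadjusted p under 0.05 and 52 with DESeq2, and 15 without day 14 sham replicate 3.

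In passage 2, Ccl8 was higher at day 90 (1.10 ± 1.02 CPM, SD, n = 3, against a mean of 20.8 CPM, log2 fold change 4.23, SE 0.63, adjusted p = 0.00270). So was Gdf15, a stress-induced TGF-beta family member (13.0 ± 6.12 against 66.3 ± 12.3 CPM, 2.36, SE 0.36, adjusted p = 0.00272). The acute phase gene Saa1 (3.45, SE 0.77) and Bcl3, an atypical inhibitor of NF-kappaB (1.42, SE 0.27), were 2 higher of 23 NF-kappaB genes, with 4 higher adjusted over the list alone. Neat1, a nuclear long noncoding RNA, was higher by 2.67 (SE 0.56). Rpph1, the RNA of ribonuclease P (−2.11, SE 0.35, adjusted p = 0.00696), and the small nucleolar RNA Snora30 (−1.97, SE 0.44) were lower. So were the Notch target Hes1 (−1.56, SE 0.34) and the clock gene Per1 (−1.23, SE 0.25). How Rpph1 and Snora30 entered libraries primed at the poly(A) tail was not tested, so their counts may not measure their expression. The lower cell cycle (7 of 39 adjusted over the list alone, adjusted p = 0.921 with an estimated correlation), nuclear OXPHOS (9 of 35 adjusted over the list alone, adjusted p = 0.736 with an estimated correlation), and cholesterol lists (adjusted p = 0.921 with an estimated correlation) had 0 members called over all genes. So had the lower myoepithelial lists (2 adjusted over the list alone, adjusted p = 0.736 with an estimated correlation) and the interferon list (adjusted p = 0.921 with an estimated correlation). The interferon median was 0.42, but −0.84 with the Gm42418 share as a covariate and −0.0158 without day 14 sham replicate 1, so no direction is given. edgeR called 45 genes, 26 higher and 19 lower, against 1448 at an unadjusted p under 0.05 and 117 with DESeq2. With total counts as scaling it called 305, 287 higher and 18 lower. The Gm42418 share separated these groups, at 28.4%, 25.5% and 22.6% at day 14 and 15.5%, 14.3% and 13.1% at day 90. With it as a covariate edgeR called 1 gene, and each gene named here lost its call. The 45 genes kept their sign, but their median absolute log2 fold change went from 1.42 to 1.22 and their median SE from 0.28 to 0.35, so day and share cannot be separated here. The calls were 18, 6 and 3 without day 14 sham replicate 1, 2 or 3 and 7 without day 90 sham replicate 2 or 3. Ccl8 and Gdf15 lost theirs without day 14 sham replicate 3 (adjusted p up to 0.0574). The other named genes lost theirs without 3 or more of the 6 libraries (adjusted p up to 0.216).

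The 4 IR effects were compared across the 10563 tested genes. They share no library, though passage 2 is grown from passage 1, and genes are not independent replicates, so no p was computed. The correlation r of the log2 fold changes was 0.63 between the passages at day 90, 0.50 between day 14 and day 90 in passage 2, 0.44 between day 14 passage 2 and day 90 passage 1, and 0.24 between the days in passage 1. It was 0.10 between the passages at day 14 and 0.10 between day 14 passage 1 and day 90 passage 2, but 0.20 and 0.18 over the 9481 genes with a mean of at least 5 CPM. Of genes called in both day 90 passages, 3 were higher in both and 1 lower in both, where independent lists would share 0.09 and 0.04. Between day 14 and day 90 in passage 2, 2 genes were called higher in both (Krt8 and Wfdc2), against 0.06. Between day 14 passage 1 and day 90 passage 2, 4 were called higher in both (0.92 by independent lists), 2 lower in both (0.10) and 3 in opposite directions.

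**Figure D2:**
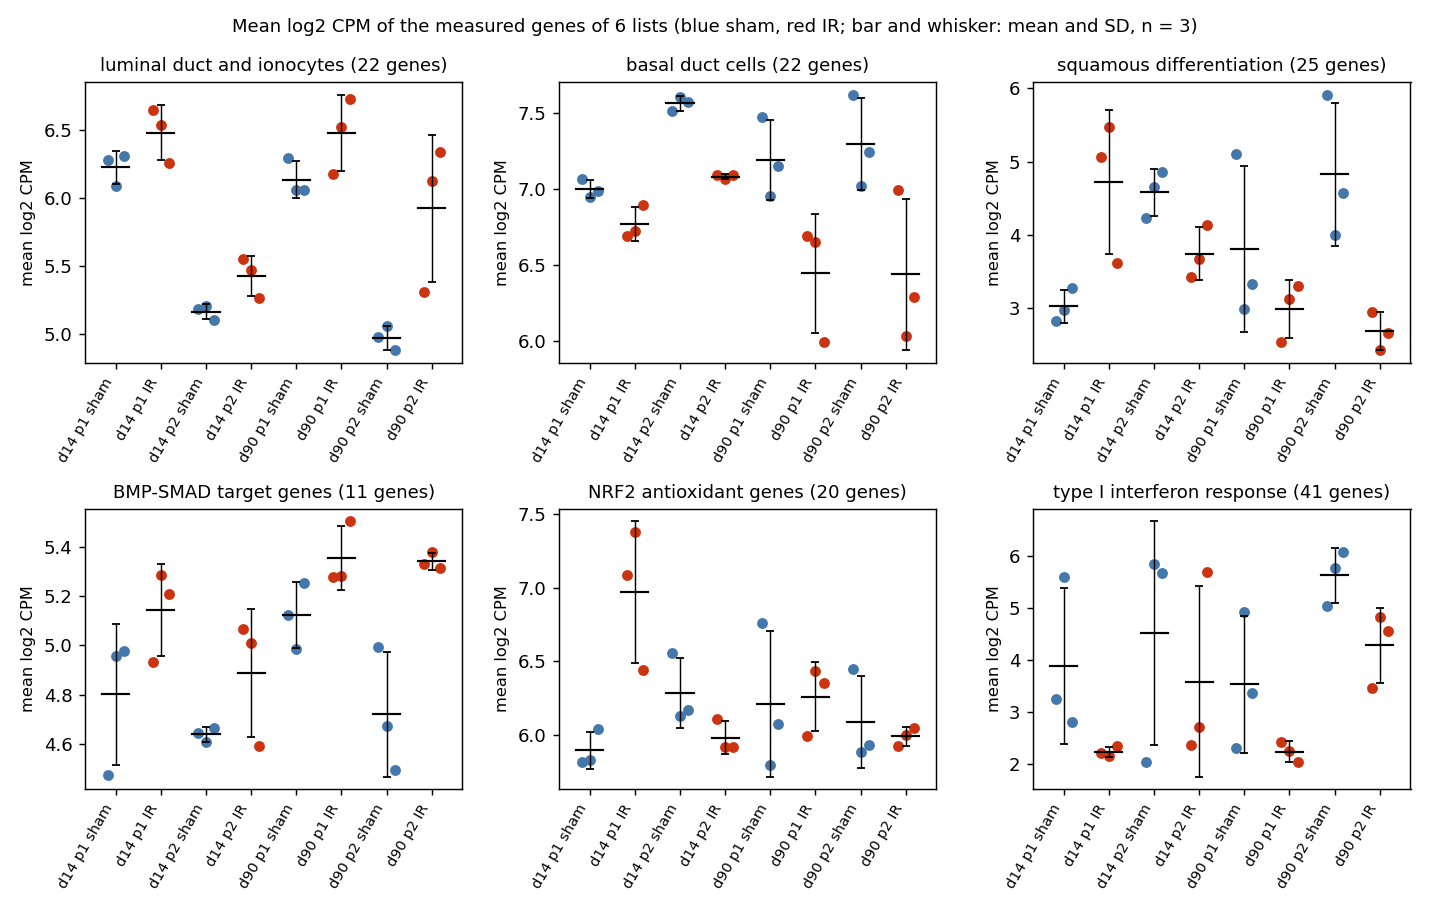
Each point is the mean log2 CPM of the tested genes of a list in 1 library, for the 8 groups on the x axis (d, day and p, passage), with sham in blue, IR in red, and the mean and SD of the 3 libraries as bar and whisker, and each y axis has its own range. The interferon list ranged from 2.02 to 6.06 between libraries, and replicates lay far apart in some groups, such as sham at day 14, and close together in both IR groups of passage 1 (2.15 to 2.34 and 2.02 to 2.42).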

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

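The interaction tests of this part were fixed beforehand. How often other splits of the libraries gave as many genes was tested after the results were seen. The results given here are differences of the IR effect between days or passages, each by a test of the difference itself. Between days in passage 1, the IR effect on Tmprss4 differed by a log2 of −2.85 (SE 0.39, edgeR adjusted p = 0.00222), with the IR mean above the sham mean at day 14 and below it at day 90. Its call held under every alternative run, with adjusted p from 3.57e-17 to 0.0261. The IR effect on Car6 differed by −4.76 (SE 0.78, adjusted p = 0.0282), also upwards at day 14 and downwards at day 90, and lost its call with only the compared groups fitted and without 8 single libraries named in the report (adjusted p from 6.09e-18 to 0.133). Between days in passage 2, the IR effect on Ccl8 differed by −5.73 (SE 0.90, adjusted p = 0.0229), and lost its call with only the compared groups fitted, without 7 single libraries named in the report, and with the Gm42418 share as a covariate (adjusted p from 5.83e-10 to 0.205). Between passages at day 14, the IR effect on the squamous differentiation list differed by a median of −2.82 (adjusted p = 0.0428 with an estimated correlation, and 0.0698 with fry, the highest over its alternatives, from 2.88e-42). The IR effect on the NRF2 antioxidant list differed by −1.18 (adjusted p = 0.0316 with an estimated correlation, and 0.0412 with fry, the highest over its alternatives, from 6.46e-28). Of 100 drawn splits, 4 gave as many genes as the 2 of the interaction with day in passage 1 (highest other 110), and 13 as many as the 1 in passage 2 (highest other 1069). Such splits carry the IR effect itself, so they do not decide whether chance can be excluded. With IR and sham exchanged at 1 day, which adds the IR effects of the 2 days, 110 genes were called in passage 1, the number of the highest split, and 519 in passage 2, which falls short of 1069, and what gave the latter was not tested.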

How the results depend on the processing

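The alternatives that use the Gm42418 share, leave out the ribosomal genes or leave out 3 libraries with a deviating share were chosen after the data were seen, as was the mean IR effect. Of 170 calls of single genes none changed sign, 81 were kept without each library in turn and 69 under every alternative run. These include 42 genes picked for the mean IR effect after its values were seen, of which 42 and 41 were kept, so that most calls in the single comparisons depended on a library or a setting. Of 93 list calls 7 were kept with an estimated correlation and 19 with fry. In the counts below, IR stands for IR against sham and IRxD and IRxP for its interactions with day and passage.

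Without a filter on low counts 22785 genes were tested and the calls were 460 (IR day 14 passage 1), 200 (day 14 passage 2), 465 (day 90 passage 1), 1044 (day 90 passage 2), 196 and 129 (IRxD in passage 1 and 2), 241 and 95 (IRxP at day 14 and 90), 539 and 704 (passage at day 14 and 90), 223 and 427 (day in passage 1 and 2). Of the IR calls 18, 3, 6 and 60 were of genes outside the filtered set, and the prior df of the spread went from 6.11 to infinite, so most rest on genes tested before, under another estimate of the spread. With only the compared groups they were 81, 0, 12 and 85 for IR in the same order, 0 for IRxD in passage 2, and 1 and 28 for day, from a spread estimated on fewer libraries. With the Gm42418 share as a covariate they were 86, 5, 0 and 225 for IR, 4 and 0 for IRxD, 1 for IRxP at day 90, 1 for day in passage 2 and 502 for the mean IR effect. DESeq2 called 123, 17 and 86 for the first 3 IR comparisons, 24 and 2 for IRxD, 20 and 3 for IRxP, and 52 and 117 for day. Without the 3 libraries of deviating share the calls were 59, 168 and 1461 for IR at day 14 passage 2 and day 90 passages 1 and 2, 32 and 22 for IRxD, 35 and 36 for IRxP, 74 for day in passage 1 and 1894 for the mean effect.

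Total counts as scaling moved the median log2 fold change of all genes by −0.19 and −0.11 for IR at day 90 in passages 1 and 2, by −0.23 and −0.16 for IRxD and by 0.23 and 0.24 for day, and by under 0.1 elsewhere. The calls with it were 20 for IR at day 90 passage 1 (3 higher, 17 lower, against 3 and 2), 12 for IRxD and 2 for day in passage 1, and 305 for day in passage 2 (287 higher, 18 lower, against 26 and 19). The split moved too for IR at day 90 passage 2 (210 higher, 227 lower, against 314 and 206) and for the mean effect (424 and 641 against 643 and 519). A stricter filter gave 5 for day in passage 1, as did leaving out the ribosomal genes.

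The labels do not say what the replicate numbers share, and in no comparison did every pair of libraries with the same number deviate together at a correlation over 0.1, the level set for a pairing. Single pairs reached 0.415, and for day in passage 1 the 3 pairs lay at 0.094 to 0.23 (other numbers −0.1 to −0.054), so a weak pairing there stays open. With the replicate block the calls were 8 for IR at day 90 passage 1, 2 for IRxD in passage 2, 2 for IRxP at day 90 and 3 for day in passage 1. With the replicate block by culture they were 2 and 6 for IRxP at day 14 and 90 (0 at day 90 with the numbers of the deposited files) and 221 and 286 for passage.

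Leaving out 1 library at a time gave 0 to 146, 0 to 38, 0 to 25 and 137 to 1194 calls for IR, 1 to 23 and 0 to 10 for IRxD, 0 to 24 and 0 to 9 for IRxP, 20 to 95 and 26 to 109 for passage, 0 to 15 and 3 to 47 for day, and 846 to 1774 for the mean effect.

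Lists whose camera test changed direction are given with their medians. They were MHC class I for IR at day 90 passage 1 with the covariate (0.18), cholesterol synthesis for IRxD in passage 2 (−0.11) and interferon for IRxP at day 14 (−0.47) without the 3 libraries, and interferon for day in passage 2 with the covariate (−0.84). Leaving out 1 library gave −0.44 to 2.54 for interferon in IRxP at day 14, where day 14 passage 2 IR replicate 3 turned it, and −0.0158 to 0.844 for interferon for day in passage 2, where day 14 passage 2 sham replicate 1 turned it. For the acinar list in passage at day 14 it gave −0.81 to 0.56. That test turned without passage 2 sham replicate 1 (0.19), while without passage 1 sham replicate 3 only the median did (0.56). Without 1 library the median alone changed sign also for the basal duct list in IR at day 14 passage 1 and for MHC class I in IR at day 14 passage 2. For each of these changes the cause was not tested, apart from the fewer libraries and the other estimates of the spread named. Depth limits genes of few CPM, since the smallest library kept 717549 counts without ribosomal genes.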

Other observations

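The mean of the 4 IR effects, the splits of the libraries for single comparisons, the interferon level, the Gm42418 share at day 90 passage 2 and the setting of IR effects against passage effects were tested after the results were seen, and the genes named in the next paragraph were chosen after their values were seen.

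In the mean over both days and passages, the called luminal genes were higher and the called basal duct genes lower in organoids of irradiated glands. At day 14 and passage 1 alone, neither the luminal list nor Krt8 was called. The IR effect there correlated with that at day 90 and passage 2 at only r = 0.10, so the mean does not show the same pattern in each comparison. In the mean of the 4 IR effects edgeR called 1162 of 10563 genes, 643 higher and 519 lower. Of these, 965 had the same sign in all 4 comparisons, which choosing genes by the mean of the same 4 effects favours, so it is no separate support. Krt8 was higher by a mean log2 of 1.12 (SE 0.10, adjusted p = 1.99e-06), Bmp4 by 2.04 (SE 0.27, adjusted p = 0.000126), Id1 by 1.63 (SE 0.25) and Id3 by 1.75 (SE 0.27). Fn1 was higher by 1.79 (SE 0.24), Npnt, a basement membrane ligand of integrins, by 2.25 (SE 0.29), and Tfcp2l1, a transcription factor of ductal epithelia, by 1.73 (SE 0.25). Trp63 was lower by −0.98 (SE 0.13), the Wnt antagonist Sfrp1 by −1.61 (SE 0.22), Gas1 by −1.75 (SE 0.24) and the transcription factor Tfap2b by −1.80 (SE 0.28). Of 22 luminal genes 10 were higher and 0 lower, of 22 basal duct genes 10 were lower and 0 higher. Krt19 of the luminal list was lower in each single comparison (−0.32 to −2.41, not called), and the basal keratins Krt5 and Krt14 were called in none. Of 11 BMP-SMAD targets 5 were higher and 1 lower, of 24 YAP genes 7 were higher and 1 lower, and of 6 myoepithelial genes 2 were lower. These 5 list calls held with an estimated correlation (adjusted p = 0.0495 each). The interferon list had 27 of 41 genes lower (adjusted p = 0.364 with an estimated correlation) and the glycolysis list 7 of 23 lower and 1 higher (adjusted p = 0.417 with an estimated correlation). In exact permutation tests of IR and sham within each day and passage, in a family of 9, the mean difference was 1.68 for Bmp4 (p = 3.75e-05, adjusted p = 6.75e-05), 1.11 for Krt8 and −0.58 for the basal duct list (p = 1.25e-05 each, the smallest these permutations can give, adjusted p = 3.75e-05). In the same permutation tests it was 0.46 for the luminal list (p = 0.000162, adjusted p = 0.000243), 0.36 for the BMP-SMAD list (p = 0.000388, adjusted p = 0.000499) and −0.52 for the squamous list (p = 0.214, adjusted p = 0.214), which averages 0.44 in passage 1 (p = 0.45) and −1.49 in passage 2 (p = 0.005). These permutations rearrange the passages independently, although passage 2 was grown from passage 1. The 9 items were chosen after results of these same libraries were seen. Krt8 was not among the genes fixed beforehand, and the lists were picked from all those tested. The adjustment over the 9 does not cover that choice, so these p-values are no separate support for Krt8 or the lists. The same limit holds for the p within single passages. Within passage 1 alone, where permutations can give 0.005 at the smallest, the exact p was 0.015 for Bmp4, 0.005 for Krt8 and the basal duct list, and 0.03 for the luminal and BMP-SMAD lists. Within passage 2 alone the exact p was 0.005 for Bmp4, Krt8 and the basal duct and luminal lists and 0.02 for the BMP-SMAD list. The count was 502 with the Gm42418 share as a covariate and 1774 without day 90 passage 2 IR replicate 1. For the 1162 genes, 1 of 100 drawn splits, the real one, gave as many and the highest other gave 193. These splits too rearrange the passages independently, so they do not settle whether chance gave the count.

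The IR effect at day 90 passage 2 ran against passaging, with log2 fold changes that correlated at r = −0.621 with those of passage 2 against passage 1 in sham at day 14, which shares no library with it. All 85 genes called in both were opposite in direction, where independent lists would share 6.15. With the Gm42418 share as a covariate in both effects r was −0.599, which argues against that share, as fitted, as the source. In the 10 splits of the 6 day 90 passage 2 libraries, too few for a share under 0.05, r was −0.614 for the real one and −0.489 to −0.091 for the others, with signs set by Krt8, which was itself called in both effects, so these signs carry no evidence. A candidate explanation, as a hypothesis, is that second-passage cultures from irradiated glands keep expression that sham cultures lose on passaging (r = −0.621), but this stays open, since r was also −0.445 for IR at day 90 passage 1 against the same passage effect, and −0.233 and −0.258 for IR at day 14 in passages 1 and 2 against the passage effect at day 90.

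The number of calls at day 90 passage 2 was weighed against library properties. With the Gm42418 share as a covariate the log2 fold changes of the 520 called genes kept a slope of 0.961 on those without it, and all 520 kept their sign. Only 218 stayed called, as the median absolute log2 fold change went from 1.39 to 1.27 and the median SE from 0.32 to 0.34. With every library thinned to 1151608 counts, 262 to 290 genes were called in 5 draws, with a median of 273, against 520. The number of calls thus depended on depth. Unequal totals alone are unlikely to account for the pattern as a whole. The thinned totals still held the ribosomal genes, so the counts left on other genes stayed unequal between libraries, and this was not tested. The share is not settled, since the slope was taken on genes called without the covariate. Without IR replicate 2 or 3, which had the higher share, 143 and 137 genes were called. Without IR replicate 1, whose share was near that of sham, it was 1194. The share, irradiation of the gland and unrecorded differences between the cultures stay open.

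The interferon list lay between a mean log2 CPM of 2.02 and 6.06 in single libraries, far apart in some groups but at 2.15 to 2.34 and 2.02 to 2.42 in the IR groups of passage 1. Immune cells in the cultures as the source of these transcripts are argued against, since the immune list had 0.38% of the CPM of the interferon list where that was highest, and was itself highest (102.9 CPM) in day 14 passage 1 IR replicate 1, where the interferon list was low (2.20), while a response of the epithelium to a few immune cells was not tested. Deviations from the group means gave r = −0.403 with the Gm42418 share (permutation p = 0.132, adjusted p = 0.264, Spearman −0.454, p = 0.0883, and r = −0.462 without the 2 farthest libraries, p = 0.104). With depth it was r = 0.212 (permutation p = 0.327, Spearman 0.170, p = 0.478, and r = 0.265 without 2, p = 0.293), so neither can be told apart from chance with 24 libraries. Over the 4 strata IR libraries were lower by a mean log2 of −1.31 (exact permutation p = 0.0142, adjusted p = 0.0160). The exact permutation p was 0.01 in passage 1 and 0.170 in passage 2. This list was chosen for the test after the results were seen, and the adjustment does not cover that choice. Irradiation stays open as an explanation.

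Splits of the same 6 libraries number 10, the real one included, too few for a share under 0.05. As many genes came from 1 of 10 for IR at day 14 passage 1 (36, highest other 0) and 2 of 10 at day 14 passage 2 (2, highest other 382, which points to a structure of the samples). At day 14 passage 2 the interferon level set sham replicates 2 and 3 and IR replicate 3 apart (5.66 to 5.83). The others lay at 2.03 to 2.70, and which split gave the 382 was not recorded. For IR at day 90 it was 1 of 10 in passage 1 (5, highest other 0) and 1 of 10 in passage 2 (520, highest other 31). For the sham groups it was 1 of 10 each for passage at day 14 (125, highest other 0) and day 90 (144, highest other 6), 10 of 10 for day in passage 1 (0, highest other 0) and 1 of 10 in passage 2 (45, highest other 2). For the interactions of IR with passage, 0 genes were called by edgeR (729 and 407 at an unadjusted p under 0.05, and 20 and 3 with DESeq2), so 100 of 100 splits gave as many by construction and decide nothing. The highest others were 560 at day 14 and 1132 at day 90. With IR and sham exchanged in 1 passage, which adds the IR effects of the 2 passages, 16 and 1132 genes were called, so at day 14 this exchange does not account for the 560.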
